A study of Homo sapiens with 6 samples.

How the data were processed

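Cultured primary human keratinocytes, the main cell type of the epidermis, were grown in a serum-free medium with epidermal growth factor and pituitary extract that keeps them self-renewing. They were transduced with retroviruses carrying short hairpin RNAs against SMC1A, against SMC3 or with a scrambled sequence, and total RNA was taken on day 10 after transduction. The RNA was labelled with biotin and hybridised to Affymetrix HG-U133 Plus arrays, which measure each gene with 1 or more probe sets. The labels give 3 groups of 2 arrays each and call the arrays of a group biological replicates; they do not say which donors or cultures stand behind them. The number of arrays limits the precision of every value.

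The deposited values are log2 signals of 54675 probe sets on 6 arrays, made with RMA (background correction, quantile normalization and summary of the probes of a set) per the submitters' processing notes; the version and settings of RMA are not stated. The values were used as deposited, with no further scaling and no pseudocount. Medians of the arrays lay between 4.87 and 4.95, the third quartiles between 7.33 and 7.48 and the highest values between 14.26 and 14.32.

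Of the probe sets, 41097 carry exactly 1 gene symbol in the platform's annotation, 1801 carry several and 11777 are not named; 62 of all probe sets are controls of the manufacturer. Probe sets with several symbols or none and the controls were left out of the comparisons, and so were 59 probe sets that could show the sex of a donor, namely those of Y chromosome genes and of the transcripts of X inactivation. Other genes of the X chromosome, SMC1A among them, were kept. Each of the remaining genes was represented by the probe set with the highest mean over the 6 arrays. A gene was tested where that probe set lay above the 40th percentile of its array on at least 2 arrays, which left 14896 of 19740 genes. Genes without a probe set of their symbol alone, among them TP63, COL17A1 and KRT6A, were not analysed here.

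The comparisons were made in limma 3.58.1 (R 4.3.3), as a linear model of the 3 groups over all 6 arrays with empirical Bayes moderation, no trend and no replicate term. Fold changes are differences of log2 means, with their standard error (SE) from the fit. All tests are two-sided except the permutation test of neighbouring genes, whose p counts only shuffled correlations at least as high as the observed one. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, with no minimum fold. Both knockdowns were compared with the control group and then directly with each other. The fit left 3 residual degrees of freedom and gained 4.18 from the prior.

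Gene lists were fixed before the data were examined: cohesin and its regulators, keratinocyte terminal differentiation, the small proline-rich and late cornified envelope proteins, differentiation transcription factors, epidermal barrier lipids, basal keratinocyte and hemidesmosome genes, epidermal self-renewal regulators, DNA replication, mitosis, p53 targets and cell cycle inhibitors, inflammatory cytokines and chemokines, antimicrobial proteins and alarmins, the type I interferon response, ribosome biogenesis, cholesterol synthesis, extracellular matrix and TGF-beta targets, hypoxia and glycolysis, the unfolded protein and integrated stress response, clustered protocadherins, HOX clusters, and markers of melanocytes, fibroblasts, immune cells and endothelial cells. These 24 lists name 684 genes, of which 537 were tested. A list with at least 5 tested members was tested for a shift against all other genes with camera, at its preset correlation of 0.01 between genes, and adjusted over 23 lists; the endothelial list had 4 tested members and was not tested. Each list test was repeated with the correlation estimated from the data and with fry, which asks whether the members move on balance one way and does not compare them with other genes. Both come with limma. With an estimated correlation, calls were also lost for lists whose estimate lay below 0.01. A lost call therefore does not by itself show correlated members.

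The genes named were also set beforehand. They are the targets; for each knockdown the 10 genes that rose and the 10 that fell most among those past the threshold whose knockdown arrays both lay on one side of both control arrays; the 5 in each direction for the direct comparison; the 10 in each direction with the largest smaller change of the pair for both knockdowns together; and up to 4 members of each list with the smallest p. Genes known only by a locus or open reading frame number were passed over. Other members of the lists that are named were chosen after their values were seen.

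Both knockdowns share the control arrays, which makes their fold changes alike even without an effect. Counts of shared genes and the correlation of fold changes were therefore set beside 100 simulated data sets with no effect, which had the same controls in common, and beside the product of the list sizes over the number of genes. Because there are only 2 control arrays, they were not split between the comparisons. The fit was tested on simulated data with known changes: a log2 change of 0.5 was recovered in 86.7% of genes for the SMC1A comparison and 82.8% for the SMC3 comparison, changes of 1 and of 2 in 100%, and 6 and 17 of 14696 unchanged genes were called. With the mitosis list lowered by 0.5 in a simulation, 1 of 23 lists was called, which was the mitosis list. Genes were drawn independently of each other there, so the simulation does not show how often lists of correlated members are called.

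Alternatives tried were no filter on dim probe sets, a filter at the 60th percentile, the mean of all probe sets of a gene, leaving out probe sets marked as matching several transcripts, quantile normalization across arrays, centring arrays on their medians, a trend with a robust prior, fits to only the groups compared, a minimum of 1.5-fold, a replicate block, camera with an estimated correlation, fry, every probe set of the targets, and leaving out each array in turn. The cohesin list without SMC1A and SMC3 was added after the data were seen. A group left with 1 array was assumed to vary like the other groups. Neither scaling moved the median of all genes by more than 0.1 on the log2 scale. RNA quality was read from the manufacturer's control probe sets. Splits of the arrays into other groups were not counted, because groups of 2 allow too few. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.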

Results

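The data are genome-wide RNA levels of keratinocytes depleted of SMC1A or SMC3, the paired core proteins of cohesin, a ring-shaped complex that holds sister chromatids together and folds chromatin into loops. The cells were kept in a medium that favours self-renewal, so the comparisons ask whether cohesin is needed to keep epidermal progenitors dividing and undifferentiated. There were 2 arrays of control cells, 2 of SMC1A knockdown cells and 2 of SMC3 knockdown cells, all from day 10 after transduction. The arrays of a group correlated at 0.997 (control), 0.998 (SMC1A) and 0.998 (SMC3) across genes, with median absolute differences of 0.109, 0.0713 and 0.0784 log2 units. Between groups the correlation was 0.943 to 0.945 for control with SMC1A arrays, 0.955 to 0.958 for control with SMC3 arrays and 0.993 for the knockdowns with each other. RNA quality was similar in all groups by the 3' minus 5' signal of GAPDH, which lay between 0.04 and 0.11 log2 units, and of ACTB, which lay between 0.33 and 0.48. The signal of 18S ribosomal RNA was 12.38 and 12.44 in control, 12.26 and 11.64 in SMC1A and 12.29 and 12.02 in SMC3 arrays, and the mean of the 24 poly-A spike probe sets was 5.77 on the array of control replicate 1 and 6.38 to 6.94 on the others. All p-values measure only the spread between these arrays, since the labels do not say which donors or cultures the replicates come from.

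Each hairpin lowered its target strongly and its partner partly. SMC1A, by its brightest probe set, had a mean log2 signal of 10.37 ± 0.05 (SD, n = 2) in control cells and 7.19 ± 0.01 (SD, n = 2) in SMC1A knockdown cells. That was a fall by 3.17 ± 0.0685 (SE, adjusted p = 1.2e-07) to 11.1% of control. SMC3, again by its brightest probe set, went from 10.07 ± 0.03 (SD, n = 2) in control to 7.45 ± 0.27 (SD, n = 2) in SMC3 knockdown cells, a log2 change of -2.63 ± 0.119 (SE, adjusted p = 4.3e-06) that left 16.2%. SMC3 RNA also fell in the SMC1A knockdown, to 43.1% of control (log2 fold change -1.22), and SMC1A RNA in the SMC3 knockdown, to 60.2% (log2 fold change -0.73). Of the other SMC1A probe sets, 2 that passed the signal filter on only 2 arrays changed by -0.94 (52.1% left) and -0.44 (73.7% left) in the SMC1A knockdown. The mean of all SMC1A probe sets changed by -1.18, so the size of the fall rests on the brightest. The other bright SMC3 probe sets showed log2 changes of -2.24 and -2.85 in the SMC3 knockdown. A dim probe set of each target (-0.16 for SMC1A and -0.12 for SMC3), which passed the signal filter on 0 arrays, did not pass the threshold.

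**Figure D1:**
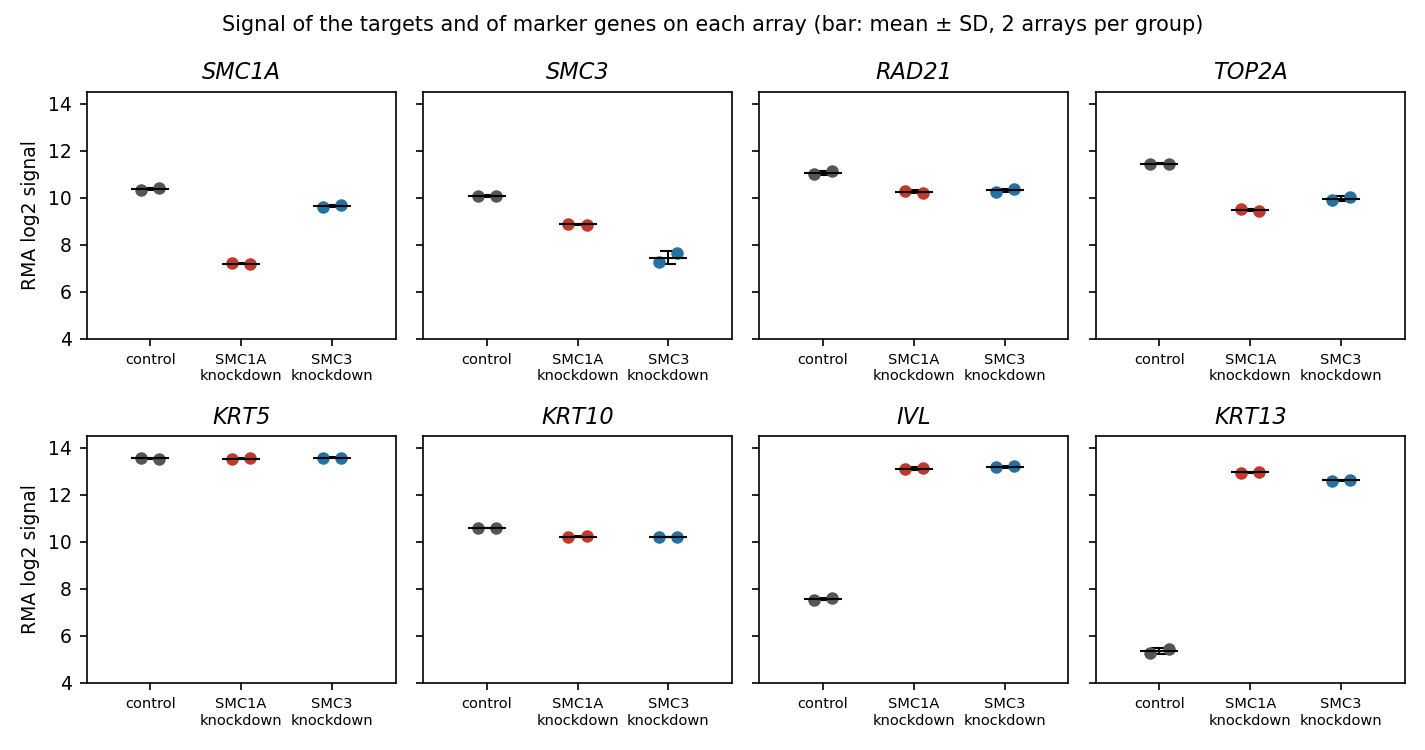
RMA log2 signal of 8 genes on each of the 6 arrays; points are arrays and bars the mean with SD of 2 arrays per group. SMC1A and SMC3 are lowest under their own hairpin, RAD21 and TOP2A lie lower in both knockdowns, KRT5 stays near the top of the scale, and IVL and KRT13 lie more than 5 log2 units above control.

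The comparison of SMC1A knockdown with control cells asks what the loss of this subunit does to progenitor cells. Depleted cells gained most of the tested genes of terminal differentiation and antimicrobial defence and lost most of those of cell division. The calcium-binding protein gene S100P rose by 8.15 ± 0.118 log2 units (SE, 2 arrays per group, 283-fold, adjusted p = 2.4e-08), from a mean of 4.87 in control to 13.01. KRT13, a keratin of mucosal linings, rose by 7.61 ± 0.0769 (195-fold), and SPRR3, a protein of the cornified envelope, by 7.36 ± 0.0671 (165-fold). Among the genes that fell most was NUF2, a kinetochore protein needed for chromosome segregation (log2 fold change -2.76).

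The other genes that rose most included SPINK6, an inhibitor of epidermal proteases (6.83), UPK1B, a uroplakin of the bladder lining (6.64), and GJA5, the gap junction protein connexin 40 (6.60). They also included ID4, an inhibitor of DNA-binding transcription factors (6.50), CRCT1, a protein of the epidermal differentiation complex (5.99), ACTG2, a smooth muscle actin (5.97), and SCEL, the cornified envelope protein sciellin (5.64). In control cells S100P, ID4 (3.52), GJA5 (3.96) and, among the genes below, CST6, FLG, DEFB1, ABCA12, IL36RN, PCDHB11, DCN, TYR, CD14 and TEK lay under the median of the arrays (4.87 to 4.95), so these rises are lower bounds. PTPRZ1, a receptor tyrosine phosphatase, fell most (log2 fold change -3.86 ± 0.0672 SE, adjusted p = 4.5e-08). It was followed by GJB6, the gap junction protein connexin 30 (-3.66), the target SMC1A, PLLP, a membrane proteolipid (-3.10), and NRCAM, a cell adhesion molecule (-3.01). Next came SLC8A1, a sodium-calcium exchanger (8.02-fold lower), CLMP, a junction adhesion molecule (-2.98), RUNX2, a transcription factor (-2.86), and AKAP12, a kinase scaffold (-2.78). The falls of CLMP, which reached 3.68, and of ESCO2 and PCDHAC2 below are lower bounds in size for the same reason.

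Genes of keratinocyte terminal differentiation rose as a group. Of 31 tested members 25 rose, 1 fell and 5 did not pass, with a median log2 fold change of 1.62 (camera adjusted p = 4.8e-11, and adjusted p = 0.0993 with an estimated correlation). Involucrin (IVL), a scaffold of the cornified envelope, rose by 5.57, the protease KLK7, which acts in shedding, by 4.77, and the protease inhibitor CST6 by 5.31. The granular layer protein filaggrin (FLG) rose by 5.03 and corneodesmosin (CDSN), an adhesive protein of the outer layers, by 4.24. The member that fell was KRT10, an early suprabasal keratin (log2 fold change -0.38), while its partner KRT1 (-0.10) and loricrin (LORICRIN, -0.03) did not pass and lay at 4.57 log2 units or below on every array. Of the small proline-rich and late envelope proteins 9 of 10 rose and none fell (median 3.16, adjusted p = 7.5e-07, and adjusted p = 0.162 with an estimated correlation), among them SPRR1A (4.74), SPRR2B (4.83) and LCE3D (4.50). Antimicrobial proteins and alarmins rose in 10 of 12 members with none falling (median 2.68, adjusted p = 3.7e-07, and adjusted p = 0.126 with an estimated correlation). Lipocalin LCN2, which binds bacterial siderophores, rose by 5.57, the protease inhibitor SLPI by 5.32, the defensin DEFB1 by 4.32 and KRT16, a keratin of stressed epidermis, by 3.45. Transcription factors of differentiation rose in 13 of 22 members, fell in 4 and did not pass in 5 (median 1.11, adjusted p = 0.0032, and adjusted p = 0.217 with an estimated correlation). GRHL3 (3.89) and GRHL1 (2.45), which drive barrier formation, OVOL1 (2.10) and GATA3 (1.77) rose, whereas CEBPB (-0.91) and NOTCH1 (-0.51) fell. Barrier lipid genes rose in 8 of 15 members and fell in 1 (median 0.51, adjusted p = 0.0097, and adjusted p = 0.322 with an estimated correlation). ABCA12, the lipid transporter of lamellar granules, rose by 4.51 and SULT2B1, which makes cholesterol sulfate, by 4.55, while ELOVL4, a fatty acid elongase, fell (-0.87).

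All 50 tested mitosis genes fell, with a median log2 fold change of -1.86 (adjusted p = 3.5e-23, and adjusted p = 0.162 with an estimated correlation). The kinetochore gene NDC80 (-2.38), the spindle checkpoint gene MAD2L1 (-2.25) and cyclin B2 (CCNB2, -1.98) were examples. Of 46 DNA replication genes 44 fell and none rose (median -1.59, adjusted p = 5.0e-19, and adjusted p = 0.162 with an estimated correlation), among them the helicase subunits CDC45 (-1.99) and MCM5 (-2.01) and cyclin E2 (CCNE2, -2.02). Ribosome biogenesis genes fell in 32 of 33 members (median -0.70, adjusted p = 7.7e-10, and adjusted p = 0.162 with an estimated correlation), including fibrillarin (FBL, -1.45). Genes of the unfolded protein and integrated stress response fell in 22 of 27 members and rose in 3 (median -0.71, adjusted p = 1.9e-06, and adjusted p = 0.162 with an estimated correlation). The serine synthesis enzymes PHGDH (-2.01) and PSAT1 (-1.47) and the stress kinase-like gene TRIB3 (-1.90) fell. Self-renewal regulators fell in 17 of 27 members and rose in 3 (median -0.31, adjusted p = 0.0077, and adjusted p = 0.322 with an estimated correlation). FOXM1, a driver of division (-1.98), the histone methyltransferase EZH2 (-1.81) and UHRF1, which maintains DNA methylation (-1.73), fell, while the inhibitors of differentiation ID2 (2.64) and ID3 (2.23) rose. Of 20 genes of cohesin and its regulators 12 fell and 2 rose (median -0.38, adjusted p = 0.0056, and adjusted p = 0.414 with an estimated correlation). Without the targets SMC1A and SMC3 the list was still called (adjusted p = 0.0263, and adjusted p = 0.422 with an estimated correlation), a test chosen after the result was seen. Besides the targets the genes that fell included sororin (CDCA5, -1.77), which protects cohesion in dividing cells, securin (PTTG1, -1.35), the acetyltransferase ESCO2 (-1.90), the ring subunit RAD21 (-0.82) and CTCF (-0.37), which marks loop ends. Whether this shift is separate from the fall of the division genes was not tested. STAG1, an alternative ring subunit, rose (0.54).

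The other lists were not called in the SMC1A knockdown. Basal keratinocyte genes rose in 5 and fell in 5 of 19 members (adjusted p = 0.614). KRT5 (-0.01), KRT14 (0.00) and the integrin ITGB1 (-0.01) did not pass, but their control means of 13.56, 14.11 and 13.43 lay near the highest values of the arrays, where a change is compressed. The basal keratin KRT15 rose (1.29) and the Notch ligand DLL1 (-2.02) and the anchoring collagen COL7A1 (-1.39) fell. Targets of p53 rose in 15 and fell in 7 of 27 members (adjusted p = 0.0545, but 0.0396 without control replicate 2 and 0.0398 after quantile normalization), with TP53I3 at 2.12 and the cell cycle inhibitor CDKN1A at 0.99. Inflammatory cytokine genes rose in 11 and fell in 10 of 26 members (adjusted p = 0.451). The antagonists IL1RN (4.05) and IL36RN (4.04) rose and IL1B, a cytokine, fell (-2.24). Interferon response genes rose in 15 and fell in 10 of 34 members (adjusted p = 0.244), with RSAD2, an antiviral enzyme, at 2.89 and SAMD9 at 1.48. IFI44 fell in its brightest probe set (-1.06) but had a change of 0.13 as the mean of its probe sets and of 1.32 without probe sets that match several transcripts. Hypoxia and glycolysis genes rose in 15 and fell in 8 of 30 members (adjusted p = 0.104), with the lipase inhibitor ANGPTL4 at 3.05 and the growth factor VEGFA at -1.60. Matrix and TGF-beta target genes rose in 13 and fell in 11 of 30 (adjusted p = 0.506), with the actin-binding TAGLN at 5.50 and the protease inhibitor SERPINE2 at -2.19. Cholesterol synthesis genes rose in 4 and fell in 9 of 18 (adjusted p = 0.538). Their median was -0.16 and fry called the list with a positive sign (adjusted p = 0.00625), with the sterol reductase TM7SF2 at 2.52. Of 10 clustered protocadherins PCDHB11 rose (0.46) and PCDHAC2 fell (-0.99). The list had an adjusted p of 0.614, with a median of 0.09 and a mean of -0.003. Of 18 HOX genes 3 rose and 4 fell (adjusted p = 0.906), with HOXC6 at 0.40 and HOXC13 at -0.49.

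Some markers of other cell types moved beside these groups. Of 15 fibroblast markers 7 rose and 2 fell (adjusted p = 0.0691, but 0.0247 without control replicate 1, 0.0415 without control replicate 2 and 0.0398 with no filter). DCN (2.23) and LUM (2.16), which are matrix proteoglycans, the surface protease FAP (2.09) and MFAP5 (1.43) rose and TWIST2 fell (-2.08). The means of LUM, 2.77 in control and 4.93 in SMC1A knockdown cells, both lay under the medians of their arrays, so the size of its rise is uncertain. Of 6 melanocyte markers MITF (1.51) and TYR (0.42) rose (list adjusted p = 0.105), and of 8 immune markers CD14 (0.67) and CD74 (0.55) rose (list adjusted p = 0.463). Of 4 endothelial markers the receptor gene TEK rose by 2.47, and PECAM1 rose by 0.33 (adjusted p = 0.0289), a call that ended without control replicate 1 (adjusted p = 0.0730), control replicate 2 (0.0890), SMC1A replicate 1 (0.118) or SMC1A replicate 2 (0.0809).

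Over all 14896 genes tested 8451 changed, 3891 upward and 4560 downward (3237 and 5057 with arrays centred on their medians). At least 2-fold changes were seen in 828 genes upward and 897 downward, at least 8-fold in 108 and 6, and at least 32-fold in 29 and 0. The groups did not overlap in 78.4% of genes, where chance gives 33.3%. Adjusted over the list alone, the called lists had 25 higher and 1 lower (terminal differentiation), 10 and 0 (small proline-rich and late proteins), 10 and 0 (antimicrobial), 13 and 5 (transcription factors), 9 and 1 (barrier lipids), 0 and 50 (mitosis), 0 and 44 (replication), 0 and 32 (ribosome biogenesis), 3 and 22 (stress response), 4 and 17 (self-renewal) and 2 and 12 (cohesin). Camera called 11 lists, 5 upward and 6 downward. With an estimated correlation it called 0 of 23 after adjustment and 7 at an unadjusted p under 0.05, and fry called 19. A minimum of 1.5-fold lowered the number of changed genes to 3795.

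Knockdown of SMC3 against control asks the same of the partner subunit. The cells again gained most of the tested genes of terminal differentiation and antimicrobial defence and lost most of those of division. KRT13 rose by 7.27 ± 0.0769 log2 units (SE, 2 arrays per group, 154-fold, adjusted p = 1.7e-08), S100P by 7.25 ± 0.118 (152-fold) and SPRR3 by 7.17 ± 0.0671 (144-fold). SPINK6 (7.07), ID4 (6.19), UPK1B (5.85), GJA5 (5.49), IVL (5.64), TAGLN, a protein of contractile fibres (5.68), and KRTDAP, a secreted protein of differentiating keratinocytes (5.79), completed the genes that rose most. Those that fell most were PTPRZ1 (-3.30 ± 0.0672 SE, adjusted p = 9.8e-08), CLMP (-2.92), GJB6 (-2.77), PLLP (-2.64), SLC8A1 (-2.63), the target SMC3, NRCAM (-2.45), EGR1, a transcription factor induced by growth factors (-2.38), ANO1, a chloride channel (-2.36), and PAG1, a membrane adaptor (-2.27). The changes of S100P, ID4, GJA5, FLG, ABCA12, IL36RN, DCN, TEK and CD14, under the array median in control, and of CLMP (3.74) and PCDHAC2, under it in SMC3 knockdown cells, are lower bounds in size.

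Terminal differentiation genes rose in 25 of 31 members and fell in 2 in the SMC3 knockdown (median 1.59, adjusted p = 6.9e-12, and adjusted p = 0.0888 with an estimated correlation). HOPX, a homeodomain protein of the upper epidermis, rose by 5.38, CRCT1 by 5.44, FLG by 3.04 and CDSN by 1.74, while KRT10 fell (-0.40). Small proline-rich and late proteins rose in 9 of 10 members (median 3.19, adjusted p = 3.1e-07, and adjusted p = 0.176 with an estimated correlation), with SPRR1A at 4.90 and SPRR1B at 4.40. Antimicrobial proteins and alarmins rose in 9 of 12 (median 3.13, adjusted p = 3.4e-07, and adjusted p = 0.127 with an estimated correlation), with LCN2 at 5.14 and the calprotectin subunit S100A8 at 3.53. Differentiation transcription factors rose in 13 and fell in 6 of 22 members (median 0.83, adjusted p = 0.0014, and adjusted p = 0.191 with an estimated correlation), with GRHL3 at 4.02 and CEBPA at 2.32. Barrier lipid genes rose in 8 of 15 members and fell in none (median 0.40, adjusted p = 0.0013, and adjusted p = 0.197 with an estimated correlation), with ABCA12 at 4.90 and the ceramide synthase CERS3 at 1.42.

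Among lists that fell, all 50 mitosis genes were lower (median -1.42, adjusted p = 5.0e-23, and adjusted p = 0.176 with an estimated correlation), with MAD2L1 at -1.72 and the kinesin KIF20A at -1.53. DNA replication genes fell in 44 of 46 members (median -1.22, adjusted p = 1.1e-18, and adjusted p = 0.176 with an estimated correlation), with the primase PRIM1 at -1.71 and CDC45 at -1.61. Ribosome biogenesis genes fell in 32 of 33 (median -0.60, adjusted p = 8.7e-10, and adjusted p = 0.176 with an estimated correlation), with FBL at -1.14. Stress response genes fell in 21 and rose in 4 of 27 (median -0.48, adjusted p = 2.1e-05, and adjusted p = 0.176 with an estimated correlation), with TRIB3 at -1.49 and PHGDH at -1.51. Self-renewal regulators fell in 17 and rose in 2 of 27 (median -0.32, adjusted p = 0.0015, and adjusted p = 0.197 with an estimated correlation). FOXM1 (-1.54) and UHRF1 (-1.34) fell and ID3 (3.89) and ID2 (2.02) rose. Cohesin genes fell in 11 and rose in 2 of 20 (median -0.28, adjusted p = 0.0112, and adjusted p = 0.401 with an estimated correlation), with CDCA5 at -1.26. Without the targets this call ended (median -0.23, adjusted p = 0.0512, a test chosen after the result was seen). Cholesterol synthesis genes fell in 12 and rose in 2 of 18 (median -0.30, adjusted p = 0.0201, and adjusted p = 0.191 with an estimated correlation), with the isomerase EBP at -0.93 and the sterol sensor INSIG1 at -0.93.

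Interferon response genes rose in 23 and fell in 3 of 34 members in the SMC3 knockdown (median 0.54, adjusted p = 9.3e-06, and adjusted p = 0.376 with an estimated correlation). RSAD2 rose by 3.49, BST2, which tethers viruses to the cell surface, by 2.95 and SAMD9L by 1.33. Matrix and TGF-beta target genes rose in 18 and fell in 8 of 30 (median 0.38, adjusted p = 0.0112, and adjusted p = 0.376 with an estimated correlation), with the matricellular CCN2 at 1.68 and ACTA2, a smooth muscle actin, at 1.73. Hypoxia and glycolysis genes rose in 14 and fell in 5 of 30 (median 0.19, adjusted p = 0.0073, and adjusted p = 0.246 with an estimated correlation), with the glucose transporter SLC2A1 at 1.30 and ANGPTL4 at 2.28. In the same cells 6 of 15 fibroblast markers rose and 3 fell (adjusted p = 0.122, but 0.0412 without control replicate 1 and 0.0397 without control replicate 2), with FAP at 2.60, THY1 at 1.73, DCN at 0.90 and TWIST2 at -1.68. Of 6 melanocyte markers MITF rose (1.11, list adjusted p = 0.499), and of 4 endothelial markers 2 rose, with TEK at 0.92. Of 8 immune markers 3 rose (list adjusted p = 0.183), namely CD14 (0.78), CD74 (0.40) and CD1C (0.30). The call of CD74 ended without control replicate 2 (adjusted p = 0.107), SMC3 replicate 1 (0.132) or SMC3 replicate 2 (0.0883), and that of CD1C without the same arrays (0.172, 0.110 and 0.150).

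Lists not called in the SMC3 knockdown were basal keratinocyte genes (4 rose and 4 fell of 19, adjusted p = 0.778), p53 targets (13 rose and 7 fell of 27, adjusted p = 0.0926) and inflammatory cytokines (12 rose and 10 fell of 26, adjusted p = 0.481). The basal list had a median of -0.02 and a mean of 0.01, and KRT5 at 0.02 and KRT14 at 0.04, which lie near the highest values of the arrays, did not pass. TP53I3 and IL36RN rose, by 2.32 and 4.07, and IL1B fell (-1.72). Protocadherins rose in 2 and fell in 2 of 10 members (adjusted p = 0.608, median 0.06 and mean -0.008), with PCDHAC2 at -0.99. HOX genes rose in 2 and fell in 5 of 18 (adjusted p = 0.763, median 0.009 and mean -0.04), with HOXB7 at -0.43.

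In total 7668 of 14896 genes changed in the SMC3 knockdown, 3435 upward and 4233 downward (2817 and 4828 with arrays centred on their medians). At least 2-fold changes numbered 681 upward and 587 downward, at least 8-fold 92 and 1, and at least 32-fold 22 and 0. The groups did not overlap in 74.8% of genes, where chance gives 33.3%. Adjusted over the list alone, higher and lower members numbered 25 and 2 (terminal differentiation), 9 and 0 (small proline-rich and late proteins), 9 and 0 (antimicrobial), 14 and 6 (transcription factors), 8 and 0 (barrier lipids), 23 and 3 (interferon), 18 and 8 (matrix), 15 and 5 (hypoxia), 0 and 50 (mitosis), 0 and 44 (replication), 0 and 32 (ribosome biogenesis), 4 and 22 (stress response), 2 and 17 (self-renewal), 2 and 12 (cohesin) and 2 and 12 (cholesterol). Camera called 15 lists, 8 upward and 7 downward. With an estimated correlation it called 0 of 23 after adjustment and 6 at an unadjusted p under 0.05, and fry called 18. A minimum of 1.5-fold lowered the number of changed genes to 3155.

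**Figure D2:**
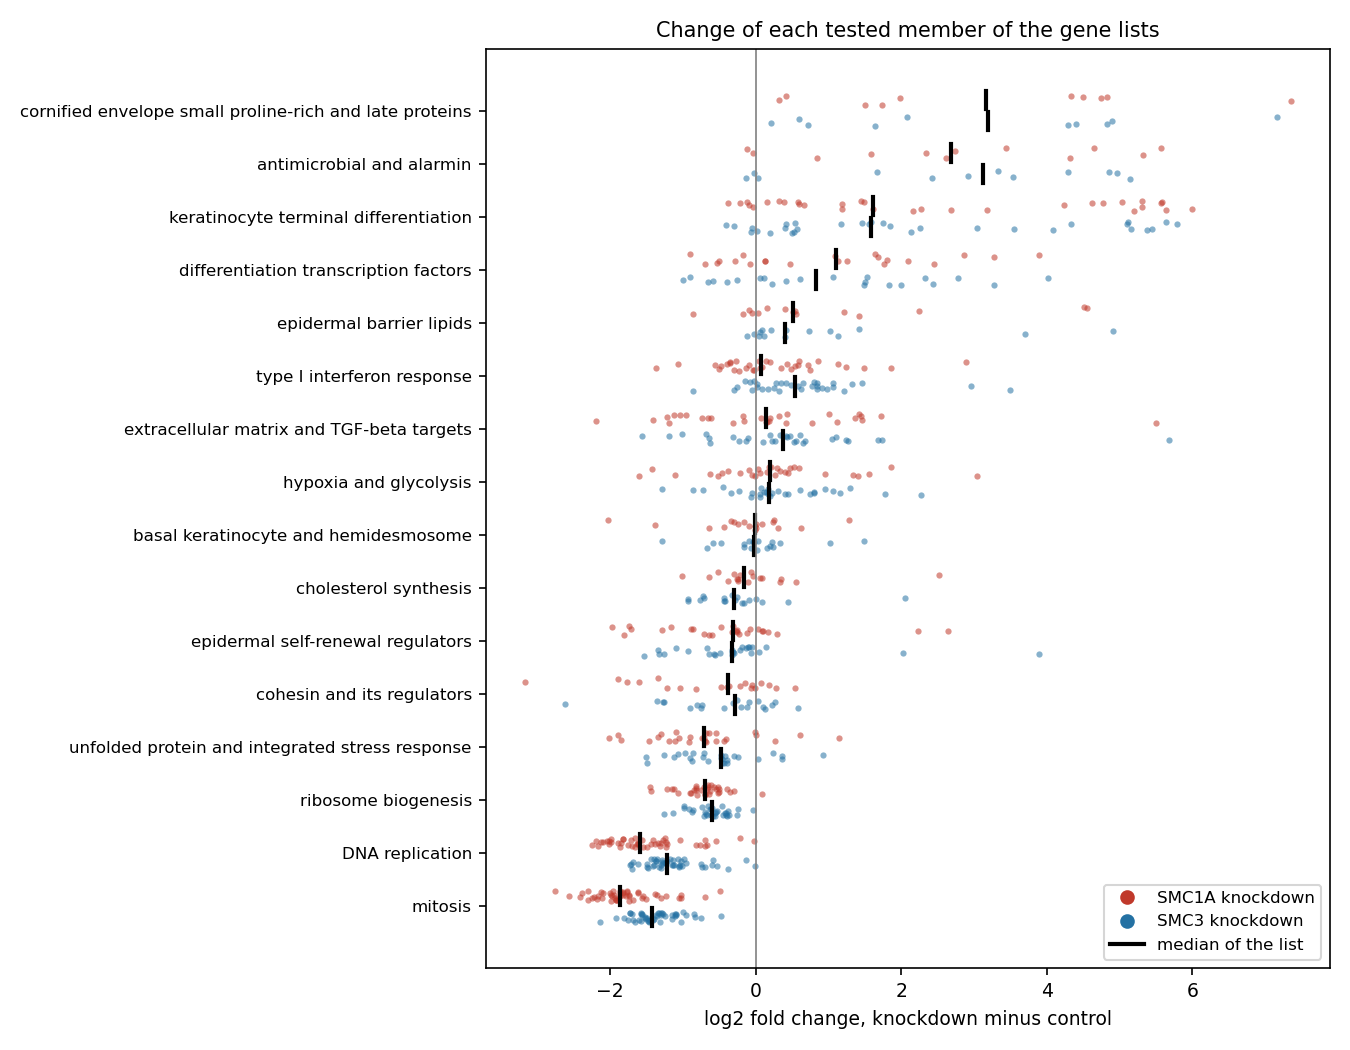
Log2 fold change of each tested member of 16 gene lists in the SMC1A (red) and SMC3 (blue) knockdown against control; each point is a gene and black bars are list medians. Differentiation, envelope and antimicrobial lists lie to the right of 0 with medians up to 3.19, and all mitosis genes lie to the left.

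Setting the knockdowns side by side asks how far the effects of the partner subunits are alike. Of the 10 genes that rose most in each knockdown 7 were the same, and of the 10 that fell most 6. Ranked by the smaller of their 2 changes, KRT13, S100P, SPRR3, SPINK6, ID4, UPK1B, IVL, TAGLN, GJA5 and CRCT1 had the largest rise in both, the last of them with log2 fold changes of 5.99 and 5.44. PTPRZ1, CLMP, GJB6, PLLP, SLC8A1, NRCAM, EGR1 (-2.48 and -2.38), ANO1 (-2.52 and -2.36), PAG1 (-2.55 and -2.27) and CCBE1, a secreted factor of lymphatic growth (-2.68 and -2.27), had the largest shared fall. In all 6658 genes changed in the same direction in both, 2887 upward and 3771 downward, which is 78.8% of the SMC1A and 86.8% of the SMC3 changes. With arrays centred on their medians the split was 2388 upward and 4274 downward, so the balance of directions depends on the scaling. Independent lists of these sizes would share 897.3 and 1296 genes, and simulated groups with no effect but the same controls shared 0 and on average 0.02. Almost no gene is called where no effect is drawn, so the simulated counts were this low by construction. They do not show how much of the sharing comes from the common controls. Only 51 genes changed in opposite directions, against 2157 for independent lists.

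The fold changes correlated across genes at 0.945 (Pearson, and 0.916 Spearman), where simulated groups with shared controls and no effect gave 0.501. The simulated value follows from sharing the controls alone. Genes are not independent replicates. The covariance was 0.469 against 0.00447 in the simulation, and 87.5% of genes had the same sign against 66.7%. The spread of fold changes was 1.15 times as large in the SMC1A as in the SMC3 knockdown. Because both comparisons use the same 2 control arrays, part of the likeness comes from those arrays. At the spread seen between arrays of a group, that part of the covariance was 0.00447, and 0.464 remained. A shift shared by both control arrays was not simulated.

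**Figure D3:**
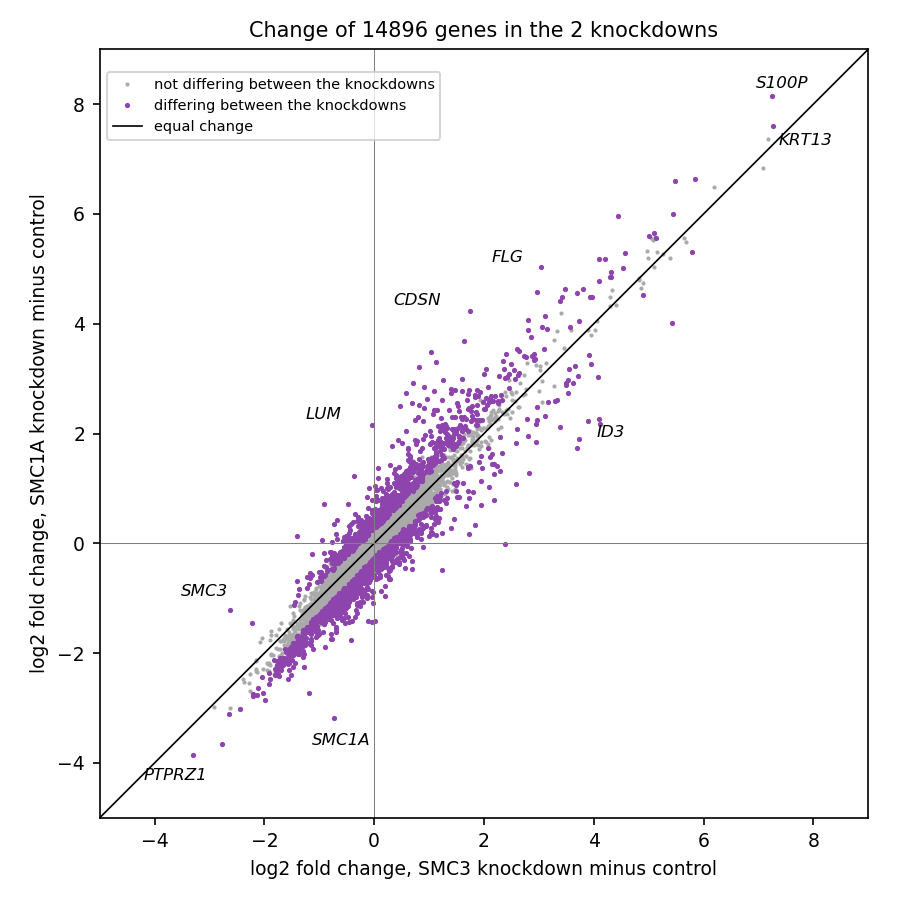
Log2 fold change against control of 14896 genes in the SMC1A knockdown (vertical axis) and the SMC3 knockdown (horizontal axis); purple points differ between the knockdowns and the diagonal marks equal change. Most genes lie near the diagonal (correlation 0.945), and CDSN, FLG and LUM lie above it and ID3 below it.

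The direct comparison of SMC1A with SMC3 knockdown cells asks where the effects differ. In SMC1A knockdown cells 39 of 50 mitosis, 24 of 46 replication and 16 of 34 interferon response genes were lower than in SMC3 knockdown cells. Of 31 terminal differentiation genes 8 were higher and 2 lower. The calls of these lists were lost with an estimated correlation (adjusted p = 0.274, 0.274, 0.410 and 0.274, in that order). CDSN was higher by 2.49 ± 0.212 log2 units (SE, 2 arrays per group, adjusted p = 0.00089), with means of 9.23 and 6.74 against 4.99 in control. LUM was higher by 2.21 ± 0.107 (adjusted p = 0.00013), at 4.93 against 2.72 with 2.77 in control. All of these means lay under the medians of their arrays, so the size of this difference is uncertain. TFPI, an inhibitor of blood clotting (2.44), CALB1, a calcium buffer (2.38), and AGTR1, the receptor of angiotensin (2.21), were also higher. Lowest relative to the SMC3 knockdown, apart from SMC1A itself (-2.44), were CHRNA9, an acetylcholine receptor subunit (-2.39 ± 0.0839 SE, adjusted p = 6.4e-05), and BBOX1, an enzyme of carnitine synthesis (-1.96). FRY (-1.94) and SPP1, the secreted protein osteopontin (-1.84), followed. None of these but SMC1A lay clearly under control in SMC1A knockdown cells. Means in control, SMC1A and SMC3 knockdown cells were 3.33, 3.31 and 5.71 for CHRNA9 and 3.08, 4.81 and 6.77 for BBOX1. For FRY they were 3.81, 5.98 and 7.93, and for SPP1 5.37, 7.27 and 9.10. TFPI, AGTR1 and, below, OCA2 and TYR in SMC3 knockdown cells and CHRNA9 (3.31) and BBOX1 in SMC1A knockdown cells lay under the median of the arrays, so these differences are lower bounds in size.

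Mitosis genes were lower in the SMC1A knockdown in 39 of 50 members and higher in 1 (median difference -0.46, adjusted p = 6.9e-22, and adjusted p = 0.274 with an estimated correlation), with the kinase CDK1 at -0.82 and cyclin A2 (CCNA2) at -0.69. The member that was higher, named after its value was seen, was ASPM (0.36). DNA replication genes were lower in 24 of 46 (median -0.34, adjusted p = 6.1e-16, and adjusted p = 0.274 with an estimated correlation), with CCNE2 at -0.64 and the clamp loader RFC4 at -0.63. Interferon response genes were lower in 16 of 34 and higher in none (median -0.32, adjusted p = 1.1e-11, and adjusted p = 0.410 with an estimated correlation), with BST2 at -1.10, LAMP3 at -0.87 and IFI44L at -0.76. Stress response genes were lower in 9 of 27 (median -0.22, adjusted p = 5.3e-06, and adjusted p = 0.274 with an estimated correlation), with the cystine transporter SLC7A11 at -0.86. Matrix and TGF-beta target genes were lower in 11 and higher in 4 of 30 (median -0.19, adjusted p = 0.00082, and adjusted p = 0.429 with an estimated correlation). The matrix proteases MMP9 (-1.30) and MMP2 (-1.16) and the collagens COL5A1 (-1.05) and COL4A2 (-0.81) were lower. Ribosome biogenesis genes passed in only 1 of 33 members, FBL (-0.31), and the list was lower (median -0.13, adjusted p = 0.0025, and adjusted p = 0.491 with an estimated correlation). The call of FBL ended without SMC1A replicate 1 (adjusted p = 0.158), SMC1A replicate 2 (0.114), SMC3 replicate 1 (0.125) or SMC3 replicate 2 (0.127). Cohesin genes were lower in 4 and higher in 1 of 20 (median -0.08, adjusted p = 0.0265, and adjusted p = 0.583 with an estimated correlation), a call that ended without SMC1A replicate 1 (adjusted p = 0.0739) or SMC3 replicate 2 (adjusted p = 0.190) and with the mean of probe sets (adjusted p = 0.0534). The targets are among them; without SMC1A and SMC3, a test chosen after the result was seen, 3 of 18 were lower and 0 higher (adjusted p = 0.0264, and adjusted p = 0.562 with an estimated correlation).

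Cholesterol synthesis genes were higher in the SMC1A knockdown in 5 of 18 members and lower in 1 (median 0.20, adjusted p = 3.8e-05, and adjusted p = 0.274 with an estimated correlation), with FDPS, which makes farnesyl diphosphate, at 0.77. Terminal differentiation genes were higher in 8 and lower in 2 of 31 (median 0.03, adjusted p = 0.0131, and adjusted p = 0.274 with an estimated correlation), with FLG at 2.00 and the shedding protease KLK7 at 0.69. Uncalled lists included basal keratinocyte genes (0 higher and 4 lower of 19, adjusted p = 0.0710, but 0.0403 without SMC3 replicate 1 and 0.0384 with no filter) and self-renewal regulators (2 and 6 of 27, adjusted p = 0.124, but 0.0403 without SMC3 replicate 1), in which ID3 differed by -1.66. Melanocyte markers were higher in 2 of 6, OCA2 (0.31) and TYR (0.48), with a list adjusted p of 0.0525 that was 0.0441 without control replicate 1, 0.0440 without control replicate 2, 0.0403 without SMC3 replicate 1 and 0.0469 after quantile normalization. The call of OCA2 ended without SMC1A replicate 1 (adjusted p = 0.224), SMC1A replicate 2 (0.151), SMC3 replicate 1 (0.197) or SMC3 replicate 2 (0.153), and that of TYR without SMC3 replicate 2 (0.0855). The remaining lists had no call, and higher and lower members are given in that order. Small proline-rich and late proteins had 0 and 0 of 10 (adjusted p = 0.443), transcription factors 3 and 1 of 22 (adjusted p = 0.594) and inflammatory cytokines 5 and 6 of 26 (adjusted p = 0.589). Barrier lipids had 3 and 2 of 15 (adjusted p = 0.863, median -0.009 and mean 0.06), p53 targets 3 and 1 of 27 (adjusted p = 0.766, median -0.007 and mean 0.01) and antimicrobial proteins 3 and 2 of 12 (adjusted p = 0.766, median -0.07 and mean 0.02). Hypoxia genes had 3 and 8 of 30 (adjusted p = 0.154), protocadherins 0 and 0 of 10 (adjusted p = 0.863), HOX genes 0 and 0 of 18 (adjusted p = 0.766) and immune markers 0 and 0 of 8 (adjusted p = 0.594). Fibroblast markers were higher in 2 and lower in 3 of 15 (adjusted p = 0.863, median -0.06 and mean 0.10), with DCN at 1.34, THY1 at -0.90 and FAP at -0.51, and of 4 endothelial markers TEK was higher (1.56).

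The knockdowns differed in 1825 of 14896 genes, 847 higher and 978 lower in SMC1A knockdown cells, of which 73 and 34 differed at least 2-fold. The groups did not overlap in 59.1% of genes, where chance gives 33.3%. Adjusted over the list alone, higher and lower members numbered 1 and 45 (mitosis), 0 and 34 (replication), 2 and 27 (interferon), 0 and 16 (stress response), 4 and 14 (matrix), 0 and 0 (ribosome biogenesis), 1 and 4 (cohesin), 9 and 1 (cholesterol) and 8 and 3 (terminal differentiation). Camera called 9 lists, 2 higher and 7 lower. With an estimated correlation it called 0 of 23 after adjustment and 4 at an unadjusted p under 0.05, and fry called 12. The number of genes was 543 without SMC1A replicate 1, 611 without SMC1A replicate 2, 609 without SMC3 replicate 1, 549 without SMC3 replicate 2 and 487 with a minimum of 1.5-fold.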

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

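None of the tests in this part was chosen only after its result was seen, although the lists and genes below drew attention because of their values. In the direct comparison, 3 of the 4 lists that were called in only 1 knockdown against control differed between the knockdowns themselves, and hypoxia genes did not pass (adjusted p = 0.154). Interferon response genes had a median of -0.32 on the log2 scale (SMC1A minus SMC3 knockdown), matrix and TGF-beta target genes one of -0.19, and cholesterol synthesis genes one of 0.20; all were called by camera and none with an estimated correlation.

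The interferon genes were higher in the SMC3 knockdown, with 16 of 34 members past the threshold. The largest difference of list medians between the arrays of a group was 0.103 log2 units, against -0.32 between the knockdowns. This argues against variation of the size seen within groups. With 2 arrays per group it cannot show how the block varies between groups handled apart. With the correlation between members estimated from the data (0.36) the full list was not called (adjusted p = 0.410). That setting called none of the lists, so it does not decide the question. Variation of the whole block between groups stays open with 2 arrays per group. A generally larger response in one knockdown is argued against by direction alone: the changes of other genes were 1.15 times as wide in the SMC1A knockdown, whereas the interferon genes rose more in the SMC3 knockdown. Scaling by this factor widened the difference to -0.38 by construction and adds no evidence. Without probe sets that match several transcripts, 29 members remained and the median difference was -0.31, so shared probe sets do not account for its size. Camera called these members at the preset correlation (adjusted p = 6.8e-10), and an estimated correlation was not tried on them. Also open is whether the difference may come from the loss of the subunit or from an effect of the hairpin sequence on other RNAs. No second hairpin against either gene was identified, and hairpin and target change together. This was not tested.

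In opposite directions 51 genes changed in the knockdowns against control; that all of them also differed in the direct comparison follows nearly from their opposite signs and adds no evidence. Examples, chosen after their values were seen, were GPX2, a glutathione peroxidase (-0.49 in the SMC1A and 1.23 in the SMC3 knockdown), COL13A1, a membrane collagen (0.72 and -0.92), and VNN1, a pantetheinase (1.22 and -0.36). Signal also appeared in probe sets that the comparisons leave out. Of 4465 probe sets that are not named and pass the signal filter, 319 were higher and 372 lower than control in both knockdowns. Of 1322 probe sets with several gene symbols that pass it, 195 were higher and 309 lower in both, and 5 of these were higher by at least 8-fold in both.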

How the results depend on the processing

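In this part only the cohesin list without its targets was chosen after the result was seen; it was called in the SMC1A knockdown and the direct comparison and not in the SMC3 knockdown (adjusted p = 0.0512). Of 331 results for named genes, 47 values under an alternative passed the threshold newly and 159 no longer passed it; IFI44 reversed in the SMC1A knockdown, from -1.06 to 0.13 with the mean of its probe sets and to 1.32 without probe sets that match several transcripts. Of 69 list results, 29 values were newly called and 40 lost, and fry called the cholesterol list in the SMC1A knockdown (median -0.16; adjusted p = 0.00625) with the opposite sign to camera. A minimum of 1.5-fold left 3795 genes (SMC1A), 3155 (SMC3), 487 (direct) and 2799 (both), by its construction. Camera with an estimated correlation called 0, 0 and 0 lists, and it estimates the correlation on 3 residual degrees of freedom. In the SMC1A knockdown the estimate was -0.0322 for terminal differentiation and -0.0157 for antimicrobial genes, below the preset 0.01. Their unadjusted camera p still went from 6.3e-12 to 0.0043 and from 8.0e-08 to 0.011. The cholesterol list in the direct comparison (-0.0376) lost its call too. These values argue against correlated members as the cause for these lists. For the others the cause was not tested. By contrast fry called 19 in the SMC1A knockdown. The correlation of fold changes was 0.941 with no filter, 0.948 with the mean of probe sets, 0.944 after quantile normalization and 0.941 to 0.947 without any 1 array. Leaving out each array in turn gave 6718 to 8396 genes (SMC1A), 5825 to 7669 (SMC3), 543 to 2210 (direct; 543 and 611 without SMC1A replicates 1 and 2, 609 and 549 without SMC3 replicates 1 and 2) and 5298 to 6765 (both); fewer arrays in the fit is part of these settings, and no other cause was tested. As the mean of all probe sets SMC1A fell by 1.18 and SMC3 by 1.96; the dim probe sets of SMC1A (-0.16) and SMC3 (-0.12) did not pass, and both lay under the filter on every array. A replicate block gave 8569, 7819 and 1824 genes and called the p53 list in the SMC1A knockdown narrowly, but arrays of the same number were not alike (correlations of their deviations 0.0652, 0.158 and 0.0055), so a pairing of the samples is not established. The counts of changed genes stayed within 1.5 times under the other filters, probe set choices, scalings and priors, from 6279 to 8703 (SMC1A), 5637 to 8080 (SMC3) and 1319 to 2712 (direct). Genes near the background, such as KRT1 and LORICRIN, cannot show a fall.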

Other observations

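In this part the tests of KRT1, LORICRIN and KRT10, and for the division genes those on other genes that fall as far, on SMC1A replicate 2, on the depth of target loss, with an estimated correlation and against the difference between arrays, were chosen only after the result was seen, and so were the groups of mucosal and smooth muscle genes. Of 29 tested genes of mucosal and bladder epithelium, 25 rose and 2 fell in the SMC1A knockdown (median log2 fold change 0.70) and 22 rose and 2 fell in the SMC3 knockdown (median 0.66). The other uroplakins, with control means under the array median, changed less than UPK1B: UPK1A (0.24 and 0.66), UPK2 (0.29 and 0.15), UPK3A (0.21 and 0.06) and UPK3B (0.43 and 0.46). UPK1A did not pass in the SMC1A knockdown, UPK2, UPK3A, MUC4 (0.21) and AGR2 (0.15) did not in the SMC3 knockdown, and CEACAM5 did not in either. Besides KRT13 and UPK1B, genes with larger rises included KRT4, the keratin partner of KRT13 (2.48 and 2.96), the protease TMPRSS11B (3.17 and 2.04) and the receptor GPRC5A (4.48 and 3.93). Others were the mucins MUC1 (2.45 and 1.71), MUC15 (2.48 and 2.62) and MUC20 (4.19 and 3.40), and MAL, a membrane sorting protein (2.57 and 3.16). The control means of TMPRSS11B (3.67), MUC15 (3.04), MUC20 (4.34) and MAL (4.76) lay under the median of the arrays, so their rises are lower bounds. CEACAM1 (-0.98 and -0.32) and TFF3 (-0.35 and -0.21, to levels under that median) fell. Of 14 contractile genes of smooth muscle, 10 rose in the SMC1A and 9 in the SMC3 knockdown and none fell, with medians of 0.62 and 0.56; ACTA2, TAGLN, TPM1 and CALD1 also belong to the matrix list. TAGLN and ACTG2 were joined by the myosin light chain MYL9 (3.17 and 3.02) and its kinase MYLK (2.69 and 2.41), while MYH11 (-0.10 and 0.09) and DES (-0.07 and 0.09), which mark mature smooth muscle, did not pass. The poly-A spikes were lowest on the array of control replicate 1, and without it 8396 genes changed in the SMC1A and 7669 in the SMC3 knockdown.

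Mucosal keratins rose while the epidermal keratins KRT1 and KRT10 and loricrin did not. Probe sets of KRT1 and LORICRIN reached at most 4.57 log2 units on any array, which cannot be told apart from background, so a rise too small to lift them over it stays open. Dim signal does not account for KRT10, whose 3 bright probe sets, all marked as matching several transcripts, were lower in both knockdowns, with -0.38 as their highest change. Whether probe sets that match several transcripts add to the rise of the mucosal genes cannot be told apart. Without them 13 of 21 genes (61.9%) rose in both knockdowns, but the genes were chosen for rising, and 7 of the 21 that rose in both have no other probe set that was tested.

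Over 96 genes of mitosis and DNA replication the median log2 fold change was -1.74 in the SMC1A and -1.31 in the SMC3 knockdown. A larger factor of response for all genes is argued against as the whole cause: after scaling by 1.14 the median difference was -0.22 and 89 of the 96 genes lay below 0, while the genes past the threshold went from 63 lower and 1 higher to 17 and 1 (adjusted p = 5.8e-11 for mitosis and 9.7e-07 for replication at the preset correlation, but 0.299 and 0.366 with an estimated one). Without SMC1A replicate 2, which has the lowest 18S value, the unscaled difference was -0.42, so that array is argued against as the cause. With a factor of 1.21 from 947 other genes that fell as far, the difference was -0.12, with 3 genes lower and 1 higher; camera still called both lists (adjusted p = 3.0e-05 and 0.0062, but 0.469 and 0.589 with an estimated correlation), yet -0.12 is under 2 times the 0.0673 between arrays of a group, so a larger response of falling genes in general cannot be told apart. By the brightest probe sets 11.1% of SMC1A was left in its knockdown against 16.2% of SMC3 in its own. The other bright SMC3 probe sets left 21.2% and 13.9%. Dimmer SMC1A probe sets left 52.1% and 73.7%, but their control means of 4.52 and 4.38 lay under the array medians. Such probe sets cannot show a deep fall. By the bright probe sets SMC1A was lost more deeply, though only 1 bright probe set measures it. Whether the depth of loss is the reason cannot be told apart from the choice of target, since each knockdown has only 1 depth.

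Cohesin folds chromosomes, so neighbouring genes might change alike when it is lost; this was tested with a prediction set beforehand. The mean changes of adjacent genes on a chromosome correlated at 0.0597 over 13615 pairs, against -0.026 to 0.027 in 1000 shuffles within chromosomes (permutation p = 0.001, the smallest they can give; adjusted p = 0.002 over 6 relations). Genes are not independent replicates, and pairs with symbols that begin alike were left out to limit the effect of gene families. Clusters of related genes with unlike symbols, such as those of the epidermal differentiation complex, stayed in, and no test without them was run. The correlation was 0.0620 for genes 2 apart (shuffles -0.0292 to 0.0308). It was 0.0246 for 5 (shuffles -0.0229 to 0.0265, permutation p = 0.003, adjusted 0.0036), 0.0364 for 10 (-0.0225 to 0.0435, p = 0.002, adjusted 0.003) and 0.0186 for 50 apart (-0.0238 to 0.0285, p = 0.013, adjusted 0.013), and these 3 lay inside the range of the shuffles. Gene level does not account for it, since 0.0475 remained after the trend with control level was removed (permutation p = 0.001; adjusted p = 0.002). The relation is weak and consistent with shared regulation of neighbours in any differentiating cell, so it does not show an effect of loops.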
